A study of Homo sapiens with 8 samples.

How the data were processed

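RNA of PMA-treated THP-1 cells was profiled on an Affymetrix 3' expression array, with 2 arrays for each of 4 groups: DMSO, CHIR99021, SB216763 and Bio-Acetoxime. Groups, doses and replicate numbers were taken from the sample labels, which give no batch, and the wells held 700000 cells and 100 ng of RNA was used, per the labels' protocols.

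The deposited values are on a log2 scale and were made by the authors with RMA, per the submitters' processing notes; the version, the software and the genome build are not given in the sources used here. RMA as usually run corrects the background, quantile normalises the arrays and summarises the probes of each probe set. That the base of the logarithm is 2 rests on RMA, since a natural logarithm is not excluded by the values. In the deposited table the median over the 8 arrays is 0, within 1e-05, for each of the 49395 probe sets, so each probe set was centred on its own median before deposit. Differences between arrays are kept by this step, while the signal level of a gene is lost. No gene can therefore be called dim or bright, no detection call was used, and a fold change near the background may understate the true change.

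Of the 49395 probe sets, 46826 were listed in the platform annotation given with the data and 2569 were not, so that they have no gene name here. Of the listed ones, 1832 matched several gene symbols and were not named, and 44988 matched 1 gene symbol and were used. Of the 102 control probe sets of the array, 96 were not listed, and the 6 that were listed were left out as well. Symbols were updated through the gene identifier, which matched the reference for 44961 of these and not for 27. No probe set without a listed gene was named. The probe sets of each gene were averaged, which gave 18132 genes, 6398 with 1 probe set and 11734 with several (at most 21). Where the probe sets of a gene measure different transcripts, or some of them respond poorly, the mean understates the change. The design set before the data were examined took the brightest probe set of each gene and left out dim genes. Neither was possible on centred values, so the mean over probe sets, until then an alternative, was used with no filter.

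Differences were tested with limma 3.58.1 in R 4.3.3: a mean per group over all 8 arrays (lmFit), contrasts between groups and moderated two-sided tests (eBayes without trend), with 4 residual and 5.31 prior degrees of freedom. Adjusted p-values follow Benjamini and Hochberg over the 18132 genes within a contrast, and a gene was called at an adjusted p under 0.05. The 6 contrasts were each inhibitor minus DMSO and each pair of inhibitors. The 4 groups share an estimate of the spread, because 2 arrays per group leave few degrees of freedom for a pair of groups. Figures were drawn with matplotlib 3.10.9.

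Before the data were examined, 23 gene lists of 513 genes were fixed from general knowledge: GSK3 and Wnt pathway components, Wnt/ß-catenin target genes, aryl hydrocarbon receptor targets, mitosis genes, DNA replication genes, cholesterol synthesis and LDL uptake genes, LXR target and cholesterol efflux genes, NF-kB and inflammatory response genes, interferon-stimulated genes, alternative activation markers, macrophage differentiation markers, myeloid progenitor markers, lymphoid, epithelial and stromal markers, chemoattractant receptors, matrix proteolysis and adhesion genes, lysosome and autophagy genes, NRF2 target genes, unfolded protein and amino acid stress genes, hypoxia and glycolysis genes, glycogen metabolism genes, MHC class II presentation genes, eicosanoid genes and ribosomal protein genes. Some genes stand in more than 1 list. Of the 513 genes, 475 were tested, and 38 were not analysed here. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, adjusted over the 23 lists of a contrast, and again with a correlation estimated from the residuals of each list and with the rotation test fry. Camera sets a list against the other genes, whereas fry asks whether the genes of a list move on balance in a direction. The counts of genes that rose and fell are given over all genes tested and adjusted over the list alone.

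The genes to name were also set by rule beforehand. GSK3A, GSK3B and CTNNB1 were always named. Against DMSO the rule took the 10 largest rises and the 10 largest falls in log2 fold change among called genes in which both treated arrays lay outside both DMSO arrays, and between inhibitors the 5 largest each way. For genes changed in the same direction by all 3 inhibitors it took the 5 with the largest mean change each way, and for each list up to 4 called members with the largest change. Part of the rule, which named the members with the highest level in lists without a call, could not be used on centred values.

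Calls shared by the 3 inhibitors, and correlations and covariances of their log2 fold changes, were set beside 20 simulated draws of unchanged groups that share the DMSO arrays and beside the overlap of independent lists. The analysis was tested on simulated data of the contrast of CHIR99021 with DMSO over 18132 genes, with known changes of 0.5, 1 and 2 on the log2 scale in 67, 67 and 66 genes. It recovered 89.6%, 100% and 100% of them, and 16 of the 209 genes called were false, or 7.66%, which is above the nominal rate of 5%. A shift of 0.3 planted in the ribosomal protein list of the contrast of SB216763 with DMSO was found by camera, with adjusted p = 3.81e-38, and 0 of the 22 other lists was called. The simulated genes were drawn independently of each other. The simulation therefore does not test camera where the genes of a list move together.

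The alternatives were array weights, a robust variance model, a fit to only the 4 arrays compared, arrays shifted to a common median, a threshold of 1 on the log2 fold change added to the adjusted p, probe sets tested separately, the replicate number as a block, and each array left out in turn. Chosen after seeing the data were the most variable probe set of each gene and a filter that kept the genes above the median variance, the split of the DMSO arrays between comparisons, and slopes between responses over all genes, from which the variance and covariance that noise and shared controls add were subtracted. Their effects are given in the closing section. Root mean square differences between arrays and the control probe sets for RNA quality and for the labelling and hybridisation spikes were described without a filter.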

Results

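Gene expression was measured on 8 Affymetrix arrays in THP-1 cells, a human monocytic leukaemia line that takes on macrophage features when exposed to the phorbol ester PMA. The cells were kept in 10 nM PMA. From 24 h after seeding they received, for 48 h, CHIR99021 at 5 µM, SB216763 at 10 µM, Bio-Acetoxime at 1 µM or the solvent DMSO, with 2 arrays per group. The labels describe the 3 compounds as inhibitors of GSK3ß, a kinase that marks ß-catenin and other proteins for degradation and restrains glycogen synthase. Each compound was used at a single dose and the doses differ, so values set side by side compare treatments and not potencies. Expression was summarised for 18132 genes. Values in parentheses after a gene symbol are log2 fold changes ± standard error, with n = 2 arrays per group. The labels do not say that the arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The small number of arrays limits the precision: the median standard error of a difference between groups was 0.0839 on the log2 scale.

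The comparisons with DMSO ask which genes changed in the macrophage-like cells under each inhibitor. With CHIR99021 the largest rises were those of CCL2 (8.21 ± 0.07) and CCL7 (7.60 ± 0.21), related chemokines that attract monocytes, which were 295-fold and 194-fold above DMSO. They were followed by MMP10 (6.21 ± 0.15), a secreted matrix metalloproteinase, GZMB (5.54 ± 0.12), the granule protease granzyme B, and CD163 (5.16 ± 0.07), the macrophage receptor for haemoglobin-haptoglobin complexes. DPP4 (4.16 ± 0.08), a cell-surface dipeptidyl peptidase, LGI2 (4.97 ± 0.07), a secreted leucine-rich repeat protein, and CHODL (4.16 ± 0.13), a membrane C-type lectin, rose as well. SCG5 (4.06 ± 0.11), a chaperone of the secretory pathway, and THBS1 (4.01 ± 0.09), the adhesive glycoprotein thrombospondin, completed the 10 genes with the largest rise. The 5 probe sets of THBS1 disagreed, with log2 fold changes from 0.15 to 7.60.

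The largest falls with CHIR99021 were in SORL1 (-3.58 ± 0.09), an intracellular sorting receptor, PROC (-3.43 ± 0.09), the anticoagulant protein C, NRGN (-3.35 ± 0.12), a calmodulin-binding protein, and FLT3 (-3.24 ± 0.14), a receptor tyrosine kinase of haematopoietic progenitors. Next came IRF8 (-3.06 ± 0.14), a transcription factor of the monocyte and dendritic cell lineage, CA2 (-3.04 ± 0.19), a carbonic anhydrase, and ASS1 (-3.03 ± 0.08), an enzyme of arginine synthesis. PDCD4 (-2.98 ± 0.08), a repressor of translation, DPEP2 (-2.86 ± 0.10), a membrane dipeptidase, and WFDC1 (-2.83 ± 0.11), a protein with a whey acidic protein domain, fell too. In each of these 20 genes both CHIR99021 arrays lay outside both DMSO arrays, as the naming rule requires, and the largest adjusted p among them was 3.06e-06, for CA2. Of the 18132 genes, 2540 rose and 2793 fell with CHIR99021, and 370 and 290 of them did so by at least 1 on the log2 scale. GSK3B, which encodes the named target, rose by 0.32 ± 0.08 (adjusted p = 0.0103), with 0.13 and 0.51 for its 2 probe sets. Of the genes called, 47.6% were higher, and 50.8% without CHIR99021 replicate 2. The call of GSK3B was lost without DMSO replicate 1 or CHIR99021 replicate 1, fits that leave a lone array in a group. The related kinase gene GSK3A (0.04 ± 0.07) did not pass, nor did CTNNB1 (-0.20 ± 0.07), which encodes ß-catenin (adjusted p = 0.0508; 0.0462 without either SB216763 array and 0.0311 with array weights).

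**Figure D1:**
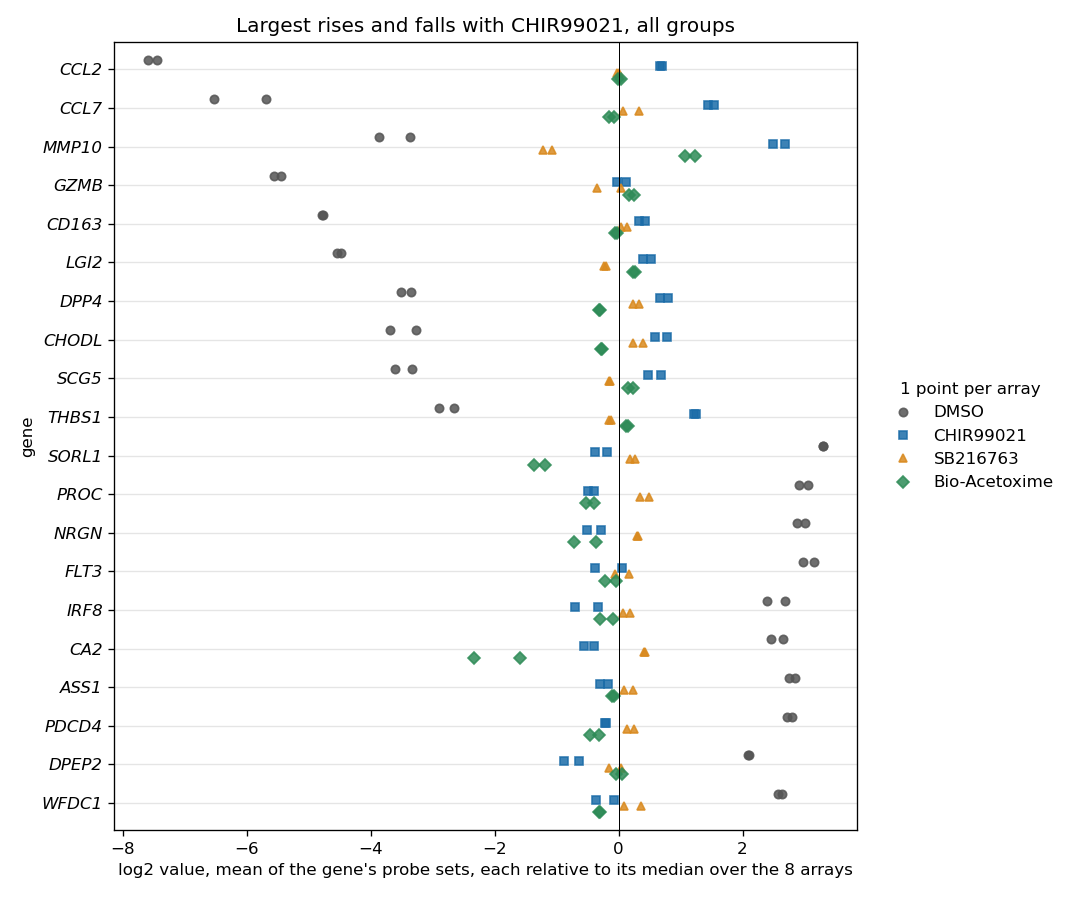
Expression of the 20 genes with the largest rises and falls under CHIR99021, with 1 point per array for all 4 groups; the x axis gives the log2 value, averaged over a gene's probe sets, relative to the median over the 8 arrays. For each gene the DMSO arrays lie apart from the arrays of all 3 inhibitors, and for CCL2 the change with CHIR99021 was 8.21.

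Cell cycle genes were lower with CHIR99021. Of 25 mitosis genes, 20 fell, 1 rose and 4 did not pass (21 and 1 adjusted over the list alone). Among them were TOP2A (-1.82 ± 0.15), the DNA topoisomerase of dividing cells, KIF20A (-1.73 ± 0.19), a kinesin of cytokinesis, and BUB1B (-1.72 ± 0.21), a spindle checkpoint kinase. The mitosis list was lower (adjusted p = 1.46e-09, and adjusted p = 0.294 with an estimated correlation). Of 28 DNA replication genes, 24 fell, 0 rose and 4 did not pass (26 and 0 adjusted over the list alone). They included the nucleotide synthesis genes TK1 (-1.85 ± 0.16), TYMS (-1.77 ± 0.19) and RRM2 (-1.63 ± 0.17) and the helicase subunit MCM7 (-1.40 ± 0.11). The DNA replication list was lower (adjusted p = 2.65e-12, and adjusted p = 0.190 with an estimated correlation).

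Genes of sterol metabolism changed with CHIR99021 in both directions. Of 19 cholesterol synthesis and LDL uptake genes, 14 rose, 0 fell and 5 did not pass (17 and 1 adjusted over the list alone). The largest changes were in DHCR7 (1.74 ± 0.19), SQLE (1.44 ± 0.08) and MSMO1 (1.21 ± 0.07), enzymes of sterol synthesis, and in the sterol sensor INSIG1 (1.25 ± 0.09). The cholesterol synthesis list was higher (adjusted p = 1.46e-09, and adjusted p = 0.0606 with an estimated correlation). Of 14 LXR target and cholesterol efflux genes, 10 fell, 1 rose and 3 did not pass (11 and 2 adjusted over the list alone). The efflux transporter ABCG1 (-1.42 ± 0.12), the apolipoprotein APOC1 (-1.24 ± 0.10) and NR1H3 (-0.90 ± 0.07), which encodes LXR alpha, fell, whereas the fatty acid desaturase SCD (1.37 ± 0.09) rose. The LXR list was lower (adjusted p = 8.84e-04, and adjusted p = 0.190 with an estimated correlation).

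Inflammatory, interferon, alternative activation and matrix lists were higher with CHIR99021. Of 23 NF-kB and inflammatory response genes, 16 rose, 2 fell and 5 did not pass (16 and 2 adjusted over the list alone). Besides CCL2, the chemokines CCL3 (3.52 ± 0.13) and CCL20 (3.33 ± 0.17) and the cytokine IL1A (2.91 ± 0.17) changed most. The NF-kB list was higher (adjusted p = 1.28e-09, and adjusted p = 0.190 with an estimated correlation). Of 26 interferon-stimulated genes, 17 rose, 0 fell and 9 did not pass (19 and 0 adjusted over the list alone). The largest rises were in EPSTI1 (2.00 ± 0.14) and in the antiviral genes IFIT1 (1.81 ± 0.23) and MX1 (1.62 ± 0.15). The interferon list was higher (adjusted p = 2.22e-08, and adjusted p = 0.190 with an estimated correlation). Of 22 alternative activation markers, 13 rose, 2 fell and 7 did not pass (13 and 2 adjusted over the list alone). With CD163 they included the anti-inflammatory cytokine IL10 (3.99 ± 0.07), the chemokine CCL18 (3.04 ± 0.18) and the mannose receptor MRC1 (2.05 ± 0.09). The alternative activation list was higher (adjusted p = 9.61e-07, and adjusted p = 0.0606 with an estimated correlation). Of 25 matrix proteolysis and adhesion genes, 17 rose, 4 fell and 4 did not pass (18 and 6 adjusted over the list alone). Besides MMP10 and THBS1, fibronectin, FN1 (3.67 ± 0.08), and the collagenase MMP1 (3.47 ± 0.15) rose most. The matrix and adhesion list was higher (adjusted p = 1.88e-06, and adjusted p = 0.141 with an estimated correlation).

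Lysosomal, stress, hypoxia and Wnt target lists were also higher with CHIR99021. Of 29 lysosome and autophagy genes, 19 rose, 0 fell and 10 did not pass (21 and 0 adjusted over the list alone). Examples were the proton pump subunit ATP6V0D2 (2.62 ± 0.11), the cholesterol transporter NPC1 (1.99 ± 0.09) and the cathepsins CTSB (1.56 ± 0.07) and CTSL (1.12 ± 0.07). The lysosome and autophagy list was higher (adjusted p = 4.16e-09, and adjusted p = 0.190 with an estimated correlation). Of 21 unfolded protein and amino acid stress genes, 9 rose, 2 fell and 10 did not pass (9 and 2 adjusted over the list alone). DDIT4 (3.35 ± 0.08), an inhibitor of mTORC1 signalling, rose most. The stress response list was higher (adjusted p = 0.00286, and adjusted p = 0.190 with an estimated correlation). Of 19 hypoxia and glycolysis genes, 12 rose, 1 fell and 6 did not pass (12 and 1 adjusted over the list alone). The glucose transporter SLC2A1 (1.34 ± 0.09) led them. The hypoxia and glycolysis list was higher (adjusted p = 2.10e-05, and adjusted p = 0.131 with an estimated correlation). Of 24 Wnt/ß-catenin target genes, 11 rose, 5 fell and 8 did not pass (11 and 5 adjusted over the list alone). The protease MMP7 (2.71 ± 0.13), the Wnt inhibitor APCDD1 (1.99 ± 0.12) and the adhesion receptor CD44 (1.15 ± 0.07) rose, and the growth regulator MYC (-1.35 ± 0.11) fell. The Wnt target list was higher (adjusted p = 0.00598, and adjusted p = 0.190 with an estimated correlation).

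The list of ribosomal protein genes, fixed beforehand as a comparison list, was slightly lower with CHIR99021, with a median log2 fold change of -0.12. A call in a comparison list is a reason for caution about small list shifts at the preset correlation. Of 22 ribosomal protein genes, 6 fell, 1 rose and 15 did not pass (7 and 1 adjusted over the list alone). The ribosomal protein list was lower (adjusted p = 0.0321, and adjusted p = 0.447 with an estimated correlation). That call was lost without DMSO replicate 1 (adjusted p = 0.0778), DMSO replicate 2 (adjusted p = 0.0543) or CHIR99021 replicate 2 (adjusted p = 0.0744) and with the most variable probe set of each gene (adjusted p = 0.0671). Markers of cell maturity went both ways. Of 23 macrophage differentiation markers, 11 fell, 6 rose and 6 did not pass (14 and 6 adjusted over the list alone), with the lysosomal protease LGMN (3.73 ± 0.08) up and the lipid carrier FABP4 (-1.50 ± 0.09) and the chitinase CHIT1 (-1.27 ± 0.13) down. The macrophage differentiation list did not pass (adjusted p = 0.0640). It passed without DMSO replicate 1 (adjusted p = 0.0480). Of 17 myeloid progenitor markers, 6 fell, 4 rose and 7 did not pass (6 and 4 adjusted over the list alone), with MYB (-2.44 ± 0.11), a transcription factor of immature cells, and MS4A3 (-2.02 ± 0.30), a marker of granulocyte-monocyte progenitors, below DMSO. The progenitor list did not pass (adjusted p = 0.331). Of 21 lymphoid, epithelial and stromal markers, 3 fell, 1 rose and 17 did not pass (3 and 1 adjusted over the list alone). This list was included to look for other cell types, and its largest change was in the endothelial and leukocyte adhesion gene PECAM1 (-1.22 ± 0.08). The lymphoid, epithelial and stromal list did not pass (adjusted p = 0.640).

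Further lists without a call under CHIR99021 held genes that changed. Of 19 chemoattractant receptors, 8 rose, 7 fell and 4 did not pass (8 and 7 adjusted over the list alone), where CCR1 (1.74 ± 0.08) and S1PR1 (1.99 ± 0.10) rose and CX3CR1 (-1.63 ± 0.08) and CXCR4 (-1.61 ± 0.15) fell. The chemoattractant receptor list did not pass (adjusted p = 0.331). Of 19 eicosanoid genes, 7 fell, 3 rose and 9 did not pass (7 and 3 adjusted over the list alone), with the leukotriene hydrolase LTA4H (-2.17 ± 0.09) lowest. The eicosanoid list did not pass (adjusted p = 0.0698). Of 19 glycogen metabolism genes, 5 fell, 4 rose and 10 did not pass (6 and 4 adjusted over the list alone), with PPP1R3B (1.47 ± 0.09), which targets a phosphatase to glycogen, highest. The glycogen list did not pass (adjusted p = 0.726). Of 22 NRF2 target genes, 7 fell, 5 rose and 10 did not pass (7 and 5 adjusted over the list alone), with the NADPH-producing enzyme ME1 (1.85 ± 0.10) highest. The NRF2 list did not pass (adjusted p = 0.979). Of 13 MHC class II presentation genes, 3 rose, 3 fell and 7 did not pass (4 and 3 adjusted over the list alone), with HLA-DMB (-1.11 ± 0.11) and the invariant chain gene CD74 (-0.84 ± 0.08) lower. The MHC class II list did not pass (adjusted p = 0.640). Of 22 GSK3 and Wnt pathway components, 8 rose, 1 fell and 13 did not pass (9 and 2 adjusted over the list alone), with the Wnt receptors FZD7 (1.91 ± 0.07) and FZD5 (1.01 ± 0.07) up and FZD2 (-1.17 ± 0.09) down. The GSK3 and Wnt component list did not pass (adjusted p = 0.102). Of 12 aryl hydrocarbon receptor targets, 2 rose, 1 fell and 9 did not pass (2 and 1 adjusted over the list alone), with the cytochrome CYP2S1 (0.96 ± 0.10) highest. The aryl hydrocarbon receptor list did not pass (adjusted p = 0.242). Fry, which does not set a list against other genes, called 6 lists under CHIR99021 that camera did not. They were the GSK3 and Wnt component (adjusted p = 7.98e-04), aryl hydrocarbon receptor (adjusted p = 0.00593) and chemoattractant receptor (adjusted p = 0.0153) lists, higher, and the progenitor (adjusted p = 0.0198), lymphoid, epithelial and stromal (adjusted p = 2.22e-04) and eicosanoid (adjusted p = 4.45e-04) lists, lower. The GSK3 and Wnt component list passed with the less variable genes left out (adjusted p = 0.0293), and the eicosanoid (adjusted p = 0.0446) and macrophage (adjusted p = 0.0284) lists passed with the most variable probe set of each gene. Both settings select on a variance to which the group differences themselves add, so these passes are not separate support.

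**Figure D2:**
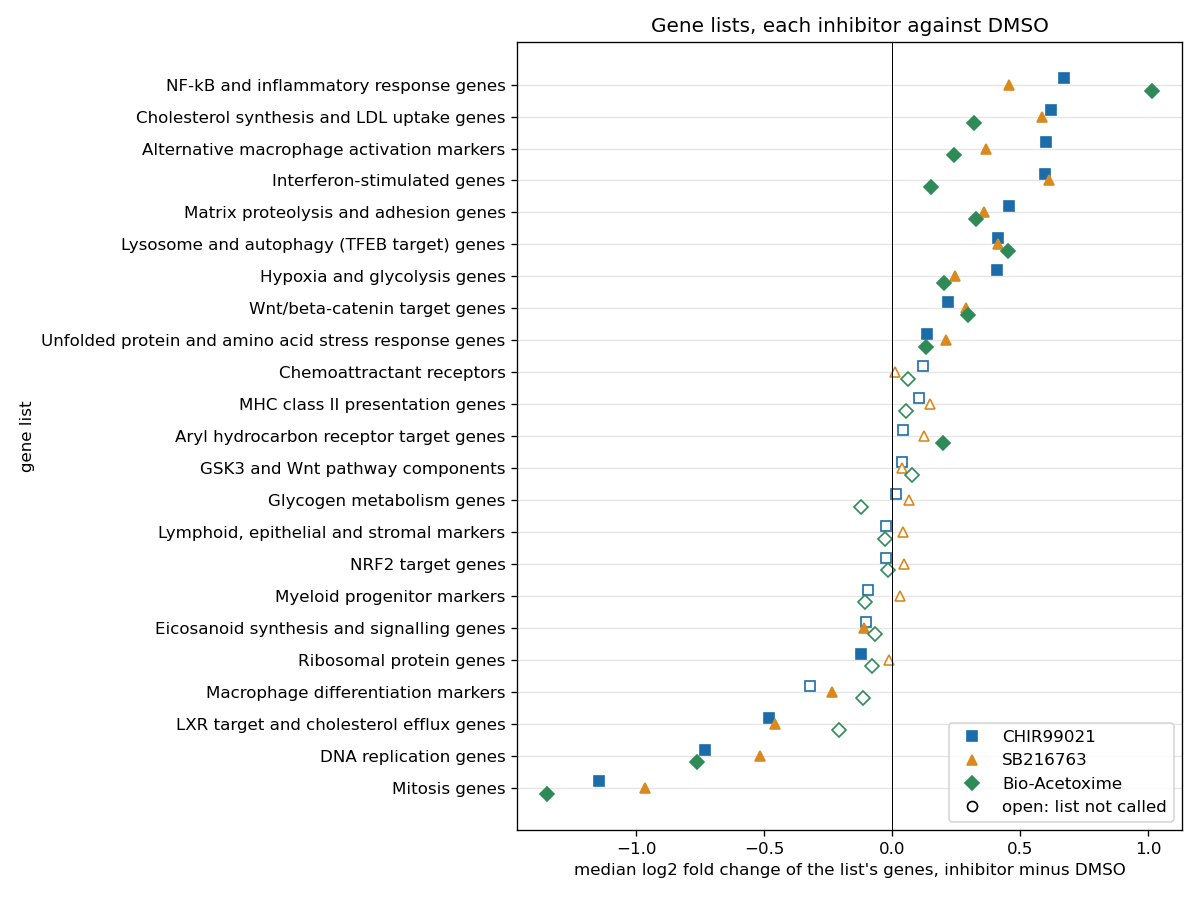
Median log2 fold change (x axis) of the genes of each of the 23 lists (y axis), each inhibitor minus DMSO, with 1 symbol per inhibitor; filled symbols mark lists called by camera at the preset correlation. The mitosis list lies at -1.15 with CHIR99021, -0.97 with SB216763 and -1.35 with Bio-Acetoxime.

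Genes were called with limma over all 8 arrays and lists with limma's camera at a preset correlation between genes, both with Benjamini-Hochberg adjustment. With a correlation estimated for each list, 0 lists passed in any comparison with DMSO, the smallest adjusted p being 0.0606 with CHIR99021, 0.0681 with SB216763 and 0.122 with Bio-Acetoxime. At an unadjusted p under 0.05 that estimate gave 4, 7 and 6 lists, and the rotation test fry called 19, 15 and 18. Among the control probe sets of the arrays, that for the middle of the 28S ribosomal RNA differed from DMSO by -0.98 ± 0.10 with CHIR99021, -0.96 ± 0.10 with SB216763 and -1.07 ± 0.10 with Bio-Acetoxime (log2 ± standard error). This difference goes along with every change against DMSO given here; over the 3 inhibitors the 3' minus 5' difference of the control probe sets differed from DMSO by -0.0187 for GAPDH and 0.0725 for ACTB. Over the same arrays the 3' and 5' probe sets of the 28S RNA differed by 0.0145 and 0.234, the 3' probe set of the 18S RNA by -0.104, the labelling spikes by -0.204 and the hybridisation spikes by 0.0744.

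SB216763 gave its largest rises in the chemokine genes CCL2 (7.51 ± 0.07) and CCL7 (6.31 ± 0.21), 182-fold and 79.5-fold above DMSO. GZMB (5.34 ± 0.12), CD163 (4.86 ± 0.07), LGI2 (4.29 ± 0.07), CHODL (3.78 ± 0.13) and DPP4 (3.71 ± 0.08) followed. The 10 largest rises ended with LBH (3.54 ± 0.08), a transcriptional cofactor, LGMN (3.49 ± 0.08) and CST7 (3.48 ± 0.08), an inhibitor of lysosomal cysteine proteases. The largest falls were in SORL1 (-3.07 ± 0.09), FLT3 (-3.01 ± 0.14), NRGN (-2.65 ± 0.12), ASS1 (-2.63 ± 0.08), PDCD4 (-2.57 ± 0.08) and PROC (-2.57 ± 0.09). Then came FAR2 (-2.55 ± 0.10), a fatty acyl-CoA reductase, IRF8 (-2.42 ± 0.14), WFDC1 (-2.39 ± 0.11) and RBP7 (-2.31 ± 0.13), a retinol-binding protein. The largest adjusted p among these 20 was 3.08e-06, for IRF8, and both SB216763 arrays lay outside both DMSO arrays in each, as the naming rule requires.

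With SB216763, 2295 genes rose and 2236 fell, 237 and 193 of them by at least 1 on the log2 scale. The share that rose, 50.7%, became 46.2% when each array was shifted to a common median, 45.5% without SB216763 replicate 1 and 56.2% without SB216763 replicate 2. CTNNB1 fell by 0.27 ± 0.07 (adjusted p = 0.0168). This call was lost without DMSO replicate 2 (adjusted p = 0.120), without SB216763 replicate 2 (adjusted p = 0.0526) and with only the 4 arrays compared (adjusted p = 0.0575). GSK3B (0.14 ± 0.08) did not pass, nor did GSK3A (adjusted p = 0.994). Of 24 Wnt/ß-catenin target genes, 11 rose, 4 fell and 9 did not pass (13 and 4 adjusted over the list alone). MMP7 (2.36 ± 0.13) and the Notch ligand JAG1 (0.90 ± 0.10) rose and MYC (-1.28 ± 0.11) fell. The Wnt target list was higher (adjusted p = 0.00307, and adjusted p = 0.156 with an estimated correlation).

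Among cell cycle and sterol genes the changes with SB216763 were these. Of 25 mitosis genes, 20 fell, 0 rose and 5 did not pass (21 and 1 adjusted over the list alone), with KIF20A (-1.70 ± 0.19) and CENPF (-1.40 ± 0.25), a kinetochore protein, as examples. The mitosis list was lower (adjusted p = 1.87e-11, and adjusted p = 0.237 with an estimated correlation). Of 28 DNA replication genes, 21 fell, 0 rose and 7 did not pass (24 and 0 adjusted over the list alone), with TK1 (-1.42 ± 0.16) and RRM2 (-1.28 ± 0.17) lower. The DNA replication list was lower (adjusted p = 1.87e-11, and adjusted p = 0.219 with an estimated correlation). Of 19 cholesterol synthesis and LDL uptake genes, 14 rose, 0 fell and 5 did not pass (16 and 0 adjusted over the list alone), with SQLE (1.24 ± 0.08) and ACAT2 (1.06 ± 0.07), a thiolase of the sterol pathway, higher. The cholesterol synthesis list was higher (adjusted p = 4.23e-09, and adjusted p = 0.0681 with an estimated correlation). Of 14 LXR target and cholesterol efflux genes, 10 fell, 1 rose and 3 did not pass (10 and 2 adjusted over the list alone), with the cholesterol exporters ABCG1 (-1.49 ± 0.12) and ABCA1 (-0.97 ± 0.09) lower. The LXR list was lower (adjusted p = 4.83e-05, and adjusted p = 0.156 with an estimated correlation).

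Inflammatory, interferon, matrix, lysosomal and stress lists were higher with SB216763. Of 23 NF-kB and inflammatory response genes, 13 rose, 1 fell and 9 did not pass (15 and 1 adjusted over the list alone), with CCL3 (2.71 ± 0.13) and the early response gene IER3 (2.20 ± 0.13) higher. The NF-kB list was higher (adjusted p = 3.88e-07, and adjusted p = 0.219 with an estimated correlation). Of 26 interferon-stimulated genes, 17 rose, 0 fell and 9 did not pass (19 and 0 adjusted over the list alone), with IFIT1 (2.03 ± 0.23) and the antiviral enzyme RSAD2 (1.56 ± 0.12) higher. The interferon list was higher (adjusted p = 4.23e-09, and adjusted p = 0.193 with an estimated correlation). Of 22 alternative activation markers, 13 rose, 1 fell and 8 did not pass (13 and 1 adjusted over the list alone), with IL10 (3.44 ± 0.07) and CCL18 (2.91 ± 0.18) higher. The alternative activation list was higher (adjusted p = 2.32e-06, and adjusted p = 0.0681 with an estimated correlation). Of 25 matrix proteolysis and adhesion genes, 13 rose, 6 fell and 6 did not pass (15 and 6 adjusted over the list alone), with THBS1 (2.64 ± 0.09) and MMP10 (2.47 ± 0.15) higher. The matrix and adhesion list was higher (adjusted p = 8.06e-04, and adjusted p = 0.183 with an estimated correlation). Of 29 lysosome and autophagy genes, 21 rose, 0 fell and 8 did not pass (21 and 0 adjusted over the list alone), with CTSB (1.37 ± 0.07) among them. The lysosome and autophagy list was higher (adjusted p = 3.22e-10, and adjusted p = 0.156 with an estimated correlation). Of 21 unfolded protein and amino acid stress genes, 8 rose, 2 fell and 11 did not pass (9 and 3 adjusted over the list alone), with DDIT4 (3.01 ± 0.08) highest. The stress response list was higher (adjusted p = 0.00464, and adjusted p = 0.219 with an estimated correlation). Of 19 hypoxia and glycolysis genes, 10 rose, 1 fell and 8 did not pass (11 and 1 adjusted over the list alone), with SLC2A1 (1.17 ± 0.09) highest. The hypoxia and glycolysis list was higher (adjusted p = 8.52e-04, and adjusted p = 0.156 with an estimated correlation).

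Other lists were lower with SB216763 or not called. Of 19 eicosanoid genes, 8 fell, 1 rose and 10 did not pass (8 and 1 adjusted over the list alone), with LTA4H (-1.92 ± 0.09) lowest. The eicosanoid list was lower (adjusted p = 0.0104, and adjusted p = 0.156 with an estimated correlation). Of 23 macrophage differentiation markers, 12 fell, 4 rose and 7 did not pass (12 and 4 adjusted over the list alone), with the lipopolysaccharide co-receptor CD14 (-1.14 ± 0.09) down and LGMN up. The macrophage differentiation list was lower (adjusted p = 0.0104, and adjusted p = 0.285 with an estimated correlation). This call was lost with fry (adjusted p = 0.113) and with the less variable genes left out (adjusted p = 0.0534). In the progenitor list the neutrophil elastase gene ELANE (1.28 ± 0.11) rose while FLT3 fell. The progenitor list did not pass (adjusted p = 0.899). The lymphoid, epithelial and stromal list did not pass (adjusted p = 0.901). Fry called the GSK3 and Wnt component (adjusted p = 0.00255) and aryl hydrocarbon receptor (adjusted p = 0.00655) lists higher with SB216763, which camera did not. With the less variable genes left out the former passed with camera as well (adjusted p = 0.0420), but the difference tested itself adds to that variance.

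Bio-Acetoxime raised CCL2 (7.53 ± 0.07) 185-fold, CCL7 (5.99 ± 0.21) 63.5-fold and GZMB (5.71 ± 0.12) 52.3-fold over DMSO. The other large rises were in MMP10 (4.77 ± 0.15), LGI2 (4.76 ± 0.07), CD163 (4.74 ± 0.07), CST7 (4.23 ± 0.08), MMP1 (4.18 ± 0.15), IL10 (4.16 ± 0.07) and OLFML2B (4.10 ± 0.10), an extracellular olfactomedin-domain protein. SORL1 (-4.57 ± 0.09) and CA2 (-4.52 ± 0.19) fell most, followed by BBOX1 (-4.14 ± 0.20), an enzyme of carnitine synthesis, PPP1R27 (-3.92 ± 0.17), a regulatory subunit of a protein phosphatase, and DHRS9 (-3.58 ± 0.12), a retinol dehydrogenase. NRGN (-3.49 ± 0.12), PROC (-3.44 ± 0.09), the G protein-coupled receptor GPR18 (-3.23 ± 0.07), FLT3 (-3.20 ± 0.14) and MS4A3 (-3.20 ± 0.30) were next. The largest adjusted p among the 20 was 4.41e-05, for MS4A3, and both Bio-Acetoxime arrays lay outside both DMSO arrays in each. In all, 2231 genes rose and 2828 fell, 309 and 325 of them by at least 1 on the log2 scale. GSK3A (0.08 ± 0.07), GSK3B (0.22 ± 0.08) and CTNNB1 (-0.13 ± 0.07) did not pass. GSK3B (adjusted p = 0.0553) passed when each array was shifted to a common median (adjusted p = 0.0366), with only the 4 arrays compared (adjusted p = 0.0455) and without either SB216763 array (adjusted p = 0.0261). It also passed with array weights (adjusted p = 0.0303). Its 2 probe sets differed, at 0.052 and 0.39, and the latter alone passed (adjusted p = 0.0174), but it was taken for its variance, to which the group difference itself adds.

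Cell cycle lists were lower with Bio-Acetoxime, and the other lists given here were higher. Of 25 mitosis genes, 21 fell, 0 rose and 4 did not pass (23 and 0 adjusted over the list alone), with TOP2A (-2.17 ± 0.15) and the spindle protein DLGAP5 (-1.99 ± 0.17) as examples. The mitosis list was lower (adjusted p = 3.52e-13, and adjusted p = 0.266 with an estimated correlation). Of 28 DNA replication genes, 25 fell, 0 rose and 3 did not pass (26 and 0 adjusted over the list alone), with TYMS (-2.12 ± 0.19) and RRM2 (-2.10 ± 0.17) lowest. The DNA replication list was lower (adjusted p = 1.27e-14, and adjusted p = 0.204 with an estimated correlation). Of 23 NF-kB and inflammatory response genes, 15 rose, 1 fell and 7 did not pass (17 and 1 adjusted over the list alone), and the neutrophil chemokine CXCL8 (3.94 ± 0.11) and CCL20 (3.77 ± 0.17) were near the top. The NF-kB list was higher (adjusted p = 7.97e-14, and adjusted p = 0.161 with an estimated correlation). Of 25 matrix proteolysis and adhesion genes, 15 rose, 4 fell and 6 did not pass (15 and 5 adjusted over the list alone), and the neutrophil collagenase MMP8 (3.21 ± 0.08) was among them. The matrix and adhesion list was higher (adjusted p = 4.52e-05, and adjusted p = 0.161 with an estimated correlation). Of 22 alternative activation markers, 10 rose, 3 fell and 9 did not pass (12 and 3 adjusted over the list alone), with the extracellular protein TGFBI (1.92 ± 0.07) higher. The alternative activation list was higher (adjusted p = 6.90e-05, and adjusted p = 0.122 with an estimated correlation). Of 19 cholesterol synthesis and LDL uptake genes, 14 rose, 1 fell and 4 did not pass (14 and 1 adjusted over the list alone), with INSIG1 (1.74 ± 0.09) highest. The cholesterol synthesis list was higher (adjusted p = 9.60e-07, and adjusted p = 0.122 with an estimated correlation). Of 29 lysosome and autophagy genes, 19 rose, 0 fell and 10 did not pass (19 and 1 adjusted over the list alone), with ATP6V0D2 (2.92 ± 0.11) highest. The lysosome and autophagy list was higher (adjusted p = 1.33e-09, and adjusted p = 0.161 with an estimated correlation).

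Targets of the aryl hydrocarbon receptor, which responds to many planar aromatic compounds, were higher as a list with Bio-Acetoxime. Of 12 aryl hydrocarbon receptor targets, 4 rose, 1 fell and 7 did not pass (5 and 1 adjusted over the list alone). The xenobiotic-metabolising enzyme CYP1B1 (1.67 ± 0.08) and the ADP-ribosyltransferase TIPARP (1.50 ± 0.10) rose most. The aryl hydrocarbon receptor list was higher (adjusted p = 0.00853, and adjusted p = 0.161 with an estimated correlation). Of 24 Wnt/ß-catenin target genes, 12 rose, 2 fell and 10 did not pass (12 and 3 adjusted over the list alone), with MMP7 (2.68 ± 0.13) and KREMEN1 (1.24 ± 0.08), a receptor of the Wnt antagonist Dickkopf, higher. The Wnt target list was higher (adjusted p = 0.00683, and adjusted p = 0.161 with an estimated correlation). Of 21 unfolded protein and amino acid stress genes, 7 rose, 3 fell and 11 did not pass (7 and 3 adjusted over the list alone), with DDIT4 (3.25 ± 0.08) highest. The stress response list was higher (adjusted p = 0.0257, and adjusted p = 0.331 with an estimated correlation). Of 19 hypoxia and glycolysis genes, 8 rose, 1 fell and 10 did not pass (11 and 1 adjusted over the list alone), with the angiogenic factor VEGFA (1.17 ± 0.07) higher. The hypoxia and glycolysis list was higher (adjusted p = 3.64e-04, and adjusted p = 0.161 with an estimated correlation). Of 26 interferon-stimulated genes, 8 rose, 2 fell and 16 did not pass (11 and 4 adjusted over the list alone), with EPSTI1 (1.31 ± 0.14) higher and XAF1 (-0.79 ± 0.09), a promoter of apoptosis, lower. The interferon list was higher (adjusted p = 0.0203, and adjusted p = 0.537 with an estimated correlation). That interferon call was lost without DMSO replicate 1 (adjusted p = 0.0862), without Bio-Acetoxime replicate 2 (adjusted p = 0.0682), with fry (adjusted p = 0.0842) and with the less variable genes left out (adjusted p = 0.0570). Of 14 LXR target and cholesterol efflux genes, 6 fell, 3 rose and 5 did not pass (8 and 3 adjusted over the list alone), with APOC1 (-1.25 ± 0.10) lower. The LXR list did not pass (adjusted p = 0.0637). The macrophage differentiation list did not pass (adjusted p = 0.381). The progenitor list did not pass (adjusted p = 0.125). The LXR and progenitor lists passed without DMSO replicate 2 (adjusted p = 0.0291 for each). The lymphoid, epithelial and stromal list did not pass (adjusted p = 0.574). Fry called 7 lists under Bio-Acetoxime that camera did not. The GSK3 and Wnt component (adjusted p = 0.00191) and chemoattractant receptor (adjusted p = 0.00476) lists were higher. The LXR (adjusted p = 0.00401), progenitor (adjusted p = 0.00763), lymphoid, epithelial and stromal (adjusted p = 6.61e-04), eicosanoid (adjusted p = 0.00171) and ribosomal protein (adjusted p = 0.0352) lists were lower. With the less variable genes left out the GSK3 and Wnt component list passed with camera as well (adjusted p = 0.0324), but the difference tested itself adds to that variance.

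The comparison of the 3 lists of calls asks how far the inhibitors changed the same genes. Against DMSO, 1473 genes rose and 1722 fell with all 3, and 180 and 159 of these changed by at least 1 on the log2 scale with each. By mean change CCL2, CCL7, GZMB, CD163 and LGI2 led the shared rises and SORL1, CA2, NRGN, FLT3 and PROC the shared falls. Independent lists of these sizes would share 39.6 rises and 53.7 falls. In 20 simulated draws of unchanged groups against shared DMSO arrays, the highest count of shared genes with limma was 0. Across genes, which are not independent replicates, log2 fold changes correlated at r = 0.925 between CHIR99021 and SB216763, 0.918 between CHIR99021 and Bio-Acetoxime and 0.870 between SB216763 and Bio-Acetoxime. Unchanged groups sharing the DMSO arrays gave simulated r of 0.498, 0.499 and 0.50 in the same order. The covariances were 0.150, 0.171 and 0.138, against simulated values of 0.00441, 0.00441 and 0.00442. With 1 DMSO array for each comparison of a pair, so that no array is shared, a setting chosen after seeing the data, the covariances were 0.143 and 0.146, 0.165 and 0.166, and 0.134 and 0.131. The counts of shared genes were not split in this way, and part of their excess may come from the shared controls. The root mean square difference between arrays over all genes, on the log2 scale, was 0.370 to 0.458 between DMSO and inhibitor arrays, 0.194 to 0.244 between arrays of different inhibitors and 0.136 to 0.173 between replicates.

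**Figure D3:**
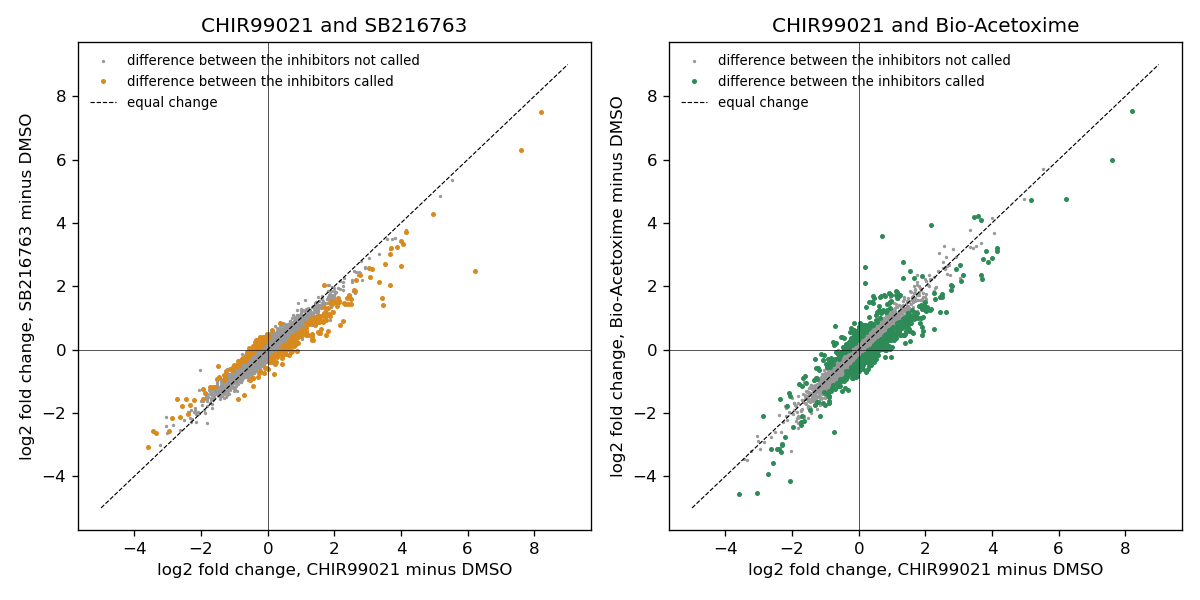
Log2 fold changes against DMSO of 18132 genes, CHIR99021 on the x axis and SB216763 (left) or Bio-Acetoxime (right) on the y axis; each point is a gene, coloured where the difference between both inhibitors was called, and the dashed line marks equal change. Most genes lie near that line, with r = 0.925 on the left and 0.918 on the right.

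These called genes differed most each way between CHIR99021 at 5 µM and SB216763 at 10 µM. MMP10 (3.74 ± 0.15) was 13.3-fold, MMP1 (2.08 ± 0.15) 4.22-fold and MMP8 (1.82 ± 0.08) 3.54-fold higher with CHIR99021, and FN1 (1.64 ± 0.08) and CXCL8 (1.38 ± 0.11) were higher as well. Lower with CHIR99021 were PPP1R27 (-1.16 ± 0.17), FABP4 (-0.99 ± 0.09), MYB (-0.88 ± 0.11), PROC (-0.86 ± 0.09) and DHRS9 (-0.78 ± 0.12). Adjusted p was 1.42e-05 for MMP10 and 0.0169 for DHRS9. Of 25 matrix proteolysis and adhesion genes, 7 were higher, 0 were lower and 18 did not pass (11 and 0 adjusted over the list alone). The matrix and adhesion list was higher (adjusted p = 6.60e-11, and adjusted p = 0.177 with an estimated correlation). Of 23 NF-kB and inflammatory response genes, 5 were higher, 0 were lower and 18 did not pass (10 and 0 adjusted over the list alone), with CCL2 (0.70 ± 0.07) among the former. The NF-kB list was higher (adjusted p = 5.02e-09, and adjusted p = 0.298 with an estimated correlation).

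Smaller shifts separated CHIR99021 and SB216763 in other lists. Of 22 alternative activation markers, 3 were higher, 0 were lower and 19 did not pass (5 and 0 adjusted over the list alone), for example IL10 (0.55 ± 0.07). The alternative activation list was higher (adjusted p = 0.00129, and adjusted p = 0.177 with an estimated correlation). Of 19 chemoattractant receptors, 5 were higher, 1 was lower and 13 did not pass (5 and 1 adjusted over the list alone), for example the oxysterol receptor GPR183 (0.88 ± 0.11). The chemoattractant receptor list was higher (adjusted p = 0.00329, and adjusted p = 0.288 with an estimated correlation). Of 19 cholesterol synthesis and LDL uptake genes, 1 was higher, 0 were lower and 18 did not pass (2 and 1 adjusted over the list alone). The cholesterol synthesis list was higher (adjusted p = 0.00456, and adjusted p = 0.288 with an estimated correlation). Of 19 hypoxia and glycolysis genes, 1 was higher, 0 were lower and 18 did not pass (1 and 0 adjusted over the list alone), for example the carbonic anhydrase CA12 (0.60 ± 0.07). The hypoxia and glycolysis list was higher (adjusted p = 0.00933, and adjusted p = 0.288 with an estimated correlation). Of 28 DNA replication genes, 1 was lower, 0 were higher and 27 did not pass (6 and 0 adjusted over the list alone). The DNA replication list was lower (adjusted p = 2.33e-05, and adjusted p = 0.479 with an estimated correlation). Of 17 myeloid progenitor markers, 1 was lower, 0 were higher and 16 did not pass (2 and 0 adjusted over the list alone). The progenitor list was lower (adjusted p = 0.00433, and adjusted p = 0.466 with an estimated correlation). Of 22 ribosomal protein genes, 2 were lower, 0 were higher and 20 did not pass (2 and 0 adjusted over the list alone). The ribosomal protein list, fixed beforehand as a comparison list, was lower (adjusted p = 0.00442, and adjusted p = 0.479 with an estimated correlation). Without SB216763 replicate 1 the progenitor (adjusted p = 0.0673) and ribosomal protein (adjusted p = 0.0591) calls were lost. With fry the chemoattractant receptor (adjusted p = 0.0690), cholesterol synthesis (adjusted p = 0.0584), replication (adjusted p = 0.193) and progenitor (adjusted p = 0.110) calls were lost. Of 22 GSK3 and Wnt pathway components, 1 was higher, 1 was lower and 20 did not pass (1 and 1 adjusted over the list alone). The GSK3 and Wnt component list was higher (adjusted p = 0.0467, and adjusted p = 0.354 with an estimated correlation). This last call was lost without CHIR99021 replicate 2 (adjusted p = 0.189), without SB216763 replicate 1 or 2 (adjusted p = 0.0591 and adjusted p = 0.133) and without either Bio-Acetoxime array (adjusted p = 0.0611 for each). Fry (adjusted p = 0.146), leaving out the less variable genes (adjusted p = 0.253) and taking each gene's most variable probe set (adjusted p = 0.101) ended it too.

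No difference between CHIR99021 and SB216763 was called for the Wnt target (adjusted p = 0.567), interferon (adjusted p = 0.930) and mitosis (adjusted p = 0.354) lists. The mitosis list passed without SB216763 replicate 2 (adjusted p = 0.00380). Fry called the lymphoid, epithelial and stromal list lower with CHIR99021 (adjusted p = 0.00179), and with the most variable probe set of each gene the LXR list passed (adjusted p = 0.00965). Of genes chosen for this after their values were seen, APCDD1 (0.05, from -0.22 to 0.31), MX1 (-0.07, from -0.41 to 0.26) and TOP2A (-0.25, from -0.60 to 0.09) did not pass, with the unadjusted 95% interval of the log2 difference in parentheses. In total 221 genes were higher and 111 lower with CHIR99021, a split of 66.6% higher that became 76.7% when each array was shifted to a common median. This count of 332 depended on single arrays. It was 26 and 50 without CHIR99021 replicates 1 and 2, 152 and 101 without SB216763 replicates 1 and 2 and 193 without either Bio-Acetoxime array. It was 183 with only the 4 arrays compared and 170 with array weights. Without CHIR99021 replicate 1 the calls of CCL2, MYB, IL10, GPR183, CA12, DHRS9 and PPP1R27 were lost, with adjusted p from 0.0518 for CCL2 to 0.0650 for PPP1R27. Those of IL10, GPR183, MYB, PPP1R27 and DHRS9 were also lost without CHIR99021 replicate 2, with adjusted p from 0.0656 for IL10 to 0.118 for DHRS9. DHRS9 also missed the threshold without SB216763 replicate 1 (adjusted p = 0.0841) or 2 (adjusted p = 0.0654).

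Between CHIR99021 at 5 µM and Bio-Acetoxime at 1 µM the largest difference was in PPBP (-2.89 ± 0.09), a platelet-derived chemokine, which was 7.39-fold lower with CHIR99021. The calcium-binding protein S100A12 (-2.42 ± 0.13), haptoglobin, HP (-1.93 ± 0.17), CXCL8 (-1.78 ± 0.11) and the natural killer cell receptor KIR2DL4 (-1.46 ± 0.09) were also lower. Higher with CHIR99021 were BBOX1 (2.07 ± 0.20), the lipoprotein lipase LPL (1.84 ± 0.10), LRFN5 (1.61 ± 0.18), a neuronal adhesion protein, CCL7 (1.61 ± 0.21) and CA2 (1.48 ± 0.19). Adjusted p was 1.45e-06 for PPBP and 0.00376 for CCL7. Of 26 interferon-stimulated genes, 11 were higher, 0 were lower and 15 did not pass (17 and 0 adjusted over the list alone), such as MX1 (1.10 ± 0.15), IFI27 (0.89 ± 0.11) and IFI44 (0.78 ± 0.07). The interferon list was higher (adjusted p = 4.05e-15, and adjusted p = 0.25 with an estimated correlation). Of 12 aryl hydrocarbon receptor targets, 2 were lower, 0 were higher and 10 did not pass (3 and 1 adjusted over the list alone), the called genes being TIPARP (-1.20 ± 0.10) and CYP1B1 (-1.01 ± 0.08). The aryl hydrocarbon receptor list was lower (adjusted p = 0.00281, and adjusted p = 0.25 with an estimated correlation).

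Other lists differed between CHIR99021 and Bio-Acetoxime, while most of their genes did not pass. Of 23 NF-kB and inflammatory response genes, 6 were lower, 2 were higher and 15 did not pass (9 and 3 adjusted over the list alone), with the chemokines CXCL1 (-0.93 ± 0.07) and CXCL3 (-1.03 ± 0.08) lower with CHIR99021. The NF-kB list was lower (adjusted p = 1.90e-05, and adjusted p = 0.430 with an estimated correlation). Of 14 LXR target and cholesterol efflux genes, 2 were lower, 0 were higher and 12 did not pass (5 and 2 adjusted over the list alone), with SMPDL3A (-0.92 ± 0.12), a phosphodiesterase of the sphingomyelinase family, lower. The LXR list was lower (adjusted p = 0.00419, and adjusted p = 0.430 with an estimated correlation). Of 19 cholesterol synthesis and LDL uptake genes, 3 were higher, 1 was lower and 15 did not pass (9 and 1 adjusted over the list alone), with SQLE (0.57 ± 0.08) higher. The cholesterol synthesis list was higher (adjusted p = 1.90e-05, and adjusted p = 0.25 with an estimated correlation). Of 22 alternative activation markers, 4 were higher, 0 were lower and 18 did not pass (6 and 1 adjusted over the list alone), with the scavenger receptor MSR1 (1.17 ± 0.07) higher. The alternative activation list was higher (adjusted p = 0.0231, and adjusted p = 0.25 with an estimated correlation). Of 19 glycogen metabolism genes, 3 were higher, 0 were lower and 16 did not pass (5 and 0 adjusted over the list alone). The glycogen list was higher (adjusted p = 0.00178, and adjusted p = 0.430 with an estimated correlation). Of 25 mitosis genes, 1 was higher, 0 were lower and 24 did not pass (1 and 0 adjusted over the list alone). The mitosis list was higher (adjusted p = 6.79e-05, and adjusted p = 0.594 with an estimated correlation). With fry the NF-kB and glycogen (adjusted p = 0.0505 for each), LXR (adjusted p = 0.0567) and mitosis (adjusted p = 0.316) calls were lost. With the less variable genes left out the alternative activation call was lost (adjusted p = 0.0658).

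Weaker calls between CHIR99021 and Bio-Acetoxime were those for replication and matrix genes. Of 28 DNA replication genes, 0 were higher, 0 were lower and 28 did not pass (0 and 0 adjusted over the list alone). The DNA replication list was higher (adjusted p = 0.0496, and adjusted p = 0.703 with an estimated correlation). Of 25 matrix proteolysis and adhesion genes, 5 were higher, 2 were lower and 18 did not pass (8 and 3 adjusted over the list alone), with MMP10 (1.44 ± 0.15) and FN1 (1.32 ± 0.08) higher. The matrix and adhesion list was higher (adjusted p = 0.0482, and adjusted p = 0.441 with an estimated correlation). Both calls were lost when each array was shifted to a common median (adjusted p = 0.0507 for each). The replication call was also lost without CHIR99021 replicate 1 (adjusted p = 0.460), Bio-Acetoxime replicate 2 (adjusted p = 0.294) or either SB216763 array (adjusted p = 0.0561 for each). The matrix call was lost without CHIR99021 replicate 1 (adjusted p = 0.141), Bio-Acetoxime replicate 1 (adjusted p = 0.104) or either SB216763 array (adjusted p = 0.0763 for each). With the less variable genes left out both were lost (adjusted p = 0.177 for replication and adjusted p = 0.259 for matrix genes), likewise with the most variable probe set of each gene (adjusted p = 0.111 and adjusted p = 0.158). Fry ended the replication call (adjusted p = 0.521). No difference was called for the Wnt target list (adjusted p = 0.636). The differences for MMP7 (0.04, from -0.25 to 0.33) and DDIT4 (0.10, from -0.07 to 0.27), given with unadjusted 95% intervals and chosen after the values were seen, did not pass. The progenitor list (adjusted p = 0.0995) passed without either DMSO array (adjusted p = 0.0298 for each) and without Bio-Acetoxime replicate 2 (adjusted p = 0.0442). In total 402 genes were higher and 189 lower with CHIR99021 than with Bio-Acetoxime. That count of 591 was 196 and 246 without CHIR99021 replicates 1 and 2, and 228 and 240 without Bio-Acetoxime replicates 1 and 2.

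Between SB216763 at 10 µM and Bio-Acetoxime at 1 µM the gene with the largest difference was again PPBP (-3.40 ± 0.09), 10.6-fold lower with SB216763. S100A12 (-3.36 ± 0.13), CXCL8 (-3.16 ± 0.11), MMP1 (-2.79 ± 0.15) and KIR2DL4 (-2.36 ± 0.09) were lower too. BBOX1 (2.87 ± 0.20), MS4A3 (2.57 ± 0.30), CA2 (2.38 ± 0.19), PPP1R27 (2.35 ± 0.17) and LPL (1.95 ± 0.10) were higher, and the largest adjusted p of these 10 was 0.00134, for MS4A3. Of 23 NF-kB and inflammatory response genes, 10 were lower, 1 was higher and 12 did not pass (12 and 1 adjusted over the list alone), with the cytokine IL1B (-1.42 ± 0.18) and CCL20 (-1.64 ± 0.17) lower. The NF-kB list was lower (adjusted p = 7.77e-14, and adjusted p = 0.198 with an estimated correlation). Of 26 interferon-stimulated genes, 13 were higher, 0 were lower and 13 did not pass (19 and 0 adjusted over the list alone), with RSAD2 (1.20 ± 0.12), MX1 (1.18 ± 0.15) and the ubiquitin-like ISG15 (0.90 ± 0.13) higher. The interferon list was higher (adjusted p = 1.55e-11, and adjusted p = 0.198 with an estimated correlation). Of 12 aryl hydrocarbon receptor targets, 3 were lower, 0 were higher and 9 did not pass (3 and 0 adjusted over the list alone), with TIPARP (-1.34 ± 0.10) and CYP1B1 (-1.20 ± 0.08) lower. The aryl hydrocarbon receptor list was lower (adjusted p = 0.00487, and adjusted p = 0.198 with an estimated correlation). Of 25 matrix proteolysis and adhesion genes, 5 were lower, 1 was higher and 19 did not pass (12 and 2 adjusted over the list alone), with MMP10 (-2.30 ± 0.15) and MMP8 (-1.59 ± 0.08) lower. The matrix and adhesion list was lower (adjusted p = 5.22e-06, and adjusted p = 0.198 with an estimated correlation).

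The replication, mitosis and progenitor lists were higher with SB216763 than with Bio-Acetoxime, while most of their genes did not pass. Of 28 DNA replication genes, 7 were higher, 0 were lower and 21 did not pass (19 and 0 adjusted over the list alone). The DNA replication list was higher (adjusted p = 1.48e-07, and adjusted p = 0.396 with an estimated correlation). Of 25 mitosis genes, 3 were higher, 0 were lower and 22 did not pass (13 and 0 adjusted over the list alone). The mitosis list was higher (adjusted p = 1.21e-05, and adjusted p = 0.466 with an estimated correlation). With fry the replication (adjusted p = 0.0633) and mitosis (adjusted p = 0.141) calls were lost. Of 17 myeloid progenitor markers, 5 were higher, 1 was lower and 11 did not pass (9 and 1 adjusted over the list alone), with MYB (1.58 ± 0.11) higher. The progenitor list was higher (adjusted p = 5.32e-04, and adjusted p = 0.389 with an estimated correlation). Of 14 LXR target and cholesterol efflux genes, 4 were lower, 1 was higher and 9 did not pass (6 and 1 adjusted over the list alone), with SMPDL3A (-0.94 ± 0.12) and ABCA1 (-0.88 ± 0.09) lower. The LXR list was lower (adjusted p = 2.01e-05, and adjusted p = 0.198 with an estimated correlation). Of 19 chemoattractant receptors, 6 were lower, 4 were higher and 9 did not pass (8 and 4 adjusted over the list alone), with GPR183 (-2.16 ± 0.11) and the formyl peptide receptor FPR2 (-1.76 ± 0.10) lower. The chemoattractant receptor list was lower (adjusted p = 8.86e-04, and adjusted p = 0.198 with an estimated correlation). Of 19 glycogen metabolism genes, 4 were higher, 0 were lower and 15 did not pass (5 and 0 adjusted over the list alone), with the glycogen-targeting subunit PPP1R3C (0.76 ± 0.12) higher. The glycogen list was higher (adjusted p = 0.00387, and adjusted p = 0.396 with an estimated correlation). The glycogen call was lost without SB216763 replicate 1 (adjusted p = 0.0768).

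No difference was called between SB216763 and Bio-Acetoxime for the Wnt target (adjusted p = 0.956) or lysosome (adjusted p = 0.440) lists. Fry called the cholesterol synthesis (adjusted p = 0.0423), alternative activation (adjusted p = 0.0226) and lymphoid, epithelial and stromal (adjusted p = 0.00505) lists higher with SB216763, which camera did not; camera put the alternative activation list lower (adjusted p = 0.956). The differences for MMP7 (-0.32, from -0.61 to -0.03) and CTSB (-0.06, from -0.22 to 0.10), given with unadjusted 95% intervals and chosen after the values were seen, did not pass. In total 715 genes were higher and 482 lower with SB216763, a split of 59.7% higher that became 48.1% when each array was shifted to a common median. The count of 1197 was 717 without SB216763 replicate 1, 458 and 470 without Bio-Acetoxime replicates 1 and 2 and 754 with array weights.

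**Figure D4:**
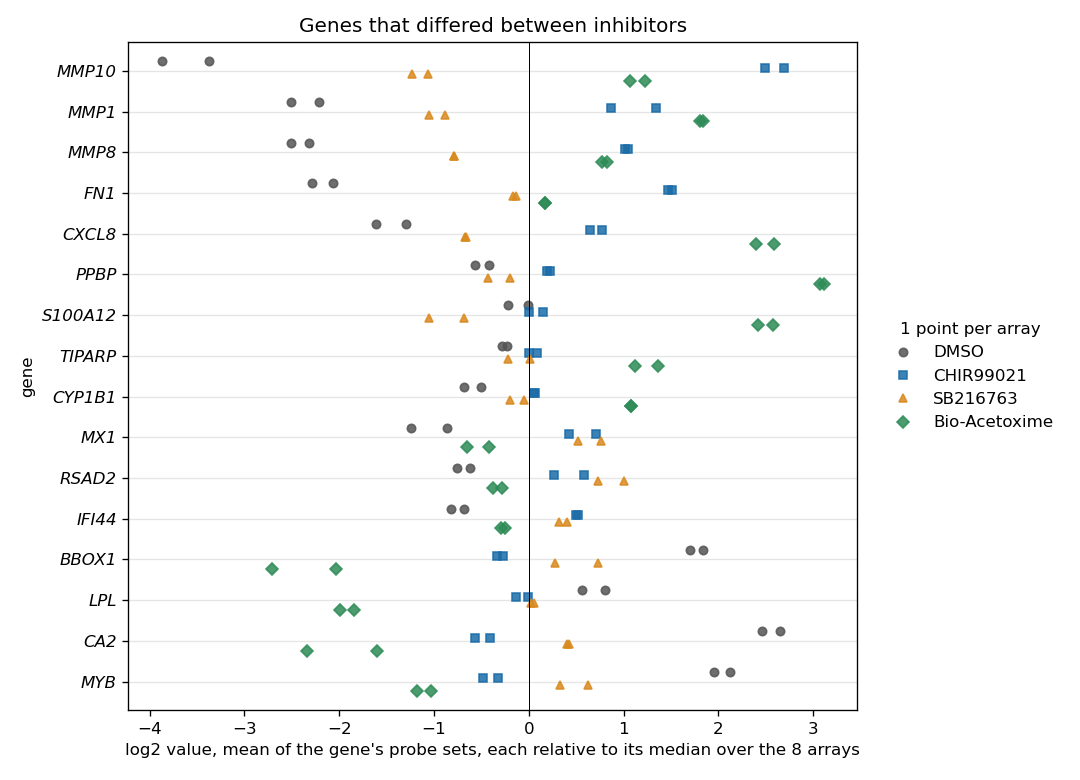
Expression of 16 genes that differed between inhibitors, picked for the plot after their values were seen, with 1 point per array for all 4 groups; the x axis gives the log2 value, averaged over a gene's probe sets, relative to the median over the 8 arrays. MMP10 is highest with CHIR99021 (3.74 above SB216763), PPBP, S100A12, TIPARP and CYP1B1 with Bio-Acetoxime, and MX1, RSAD2 and IFI44 lie lower with Bio-Acetoxime than with the other inhibitors.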

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

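The tests of RNA degradation, of aryl hydrocarbon receptor activation and of the slopes between responses were chosen only after the result was seen, and so were the genes named as examples here; the tests of differentiation and of the Wnt target list, and a test of residuals, were set beforehand.

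Between the inhibitors, 34 genes were called higher with an inhibitor and lower with another, each against DMSO, and for each of them the difference between the opposed inhibitors was itself called with limma. SB216763 and Bio-Acetoxime opposed each other in 25 of them, CHIR99021 and Bio-Acetoxime in 14 and CHIR99021 and SB216763 in 3, some genes standing in more than 1 pair. S100A12, a calcium-binding protein of neutrophils and monocytes, changed by 2.60 ± 0.13 with Bio-Acetoxime and -0.76 ± 0.13 with SB216763. GPR183, an oxysterol receptor, changed by 1.71 ± 0.11 and -0.46 ± 0.11, the endothelial and monocyte anticoagulant receptor THBD by 1.35 ± 0.11 and -0.46 ± 0.11, and CD14 by 0.37 ± 0.09 and -1.14 ± 0.09, in the same order. The metallothionein gene MT1G changed by -0.50 ± 0.08 with Bio-Acetoxime and 0.83 ± 0.08 with SB216763.

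Of the 4407 probe sets outside the gene table, 215 were called higher and 232 lower with all 3 inhibitors. The largest mean rise among the 215 was that of a probe set which matches several genes and is therefore not named, at 4.28 above DMSO on the log2 scale over the 3 inhibitors. It rose by 5.11 ± 0.24 with CHIR99021, 2.99 ± 0.24 with SB216763 and 4.73 ± 0.24 with Bio-Acetoxime.

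The DMSO arrays stand apart from all inhibitor arrays, and a difference in RNA quality stays open. On average over inhibitors the 3' minus 5' difference of GAPDH and ACTB changed by at most 0.0725 (log2). ACTB was at 0.213 and 0.175 with Bio-Acetoxime and at most 0.105 on the other arrays. The middle 28S ribosomal RNA probe set was at 1.08 and 0.886 with DMSO and differed by -1.01 with inhibitors. Other ribosomal RNA probe sets did not follow it (0.0145 and 0.234 for 28S 3' and 5', -0.104 for 18S 3'). Less advanced differentiation of the DMSO cells stays open, since the median change of macrophage markers minus that of progenitor markers was -0.215, with a bootstrap 95% interval over genes from -0.556 to 0.479. Inhibition of GSK3 by all 3 compounds stays open as well: the Wnt target list was higher with each, the largest adjusted p being 0.00683, which met the prediction set beforehand. None of the 3 calls held (adjusted p = 0.190, 0.156 and 0.161 with an estimated correlation), a requirement added after the list results were seen. No list met that requirement in any contrast, so it cannot decide the question. Fry called the Wnt list higher with each (adjusted p = 3.3e-04, 5.3e-04 and 6.8e-04). It called 19, 15 and 18 of the 23 lists, so it cannot decide either. GSK3 inhibition is left open, as a higher list does not separate it from other array differences.

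The list of aryl hydrocarbon receptor targets was higher with Bio-Acetoxime than with both other inhibitors, while fry called it higher than DMSO with those as well (adjusted p = 0.00593 with CHIR99021 and 0.00655 with SB216763). Over all genes a stronger common response with Bio-Acetoxime was hardly seen. Slopes corrected for noise and shared controls were 0.919 to CHIR99021 and 1.04 to SB216763 (at most 0.930 and 1.05 with each array left out). The list-mean ratios, 2.60 and 2.75 (at least 2.31 and 2.40), decide nothing, since the list was flagged as higher. The residual test set beforehand (mean 0.254) nearly repeats the difference of the list means from CHIR99021, 0.231, and decides nothing. Activation of the receptor by Bio-Acetoxime, a brominated indirubin derivative, is a candidate explanation, with 0.00487 as the larger adjusted p of the comparisons. It stays open, because mainly CYP1B1 and TIPARP moved. Neither camera call held (adjusted p = 0.25 and 0.198 with an estimated correlation), a requirement that no list met in any contrast.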

How the results depend on the processing

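The most variable probe set of each gene and the filter on variance were chosen after seeing the data; the other settings were fixed before. No call of a gene or list named here reversed its direction in the settings in which that gene or list was run; signs of values that were not called were not followed.

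With probe sets tested separately, the calls were 12012 for CHIR99021, 9785 for SB216763 and 11054 for Bio-Acetoxime against DMSO, 574, 955 and 2138 for CHIR99021 minus SB216763, CHIR99021 minus Bio-Acetoxime and SB216763 minus Bio-Acetoxime, and 6736 shared by all 3, since 44988 probe sets are counted in place of 18132 genes. Requiring a log2 change of at least 1 left 660, 430, 634, 18, 40, 85 and 339 in the same order, by construction. For CHIR99021 minus SB216763 the 332 genes became 183 with only the 4 arrays compared and 170 with array weights, and for SB216763 minus Bio-Acetoxime the 1197 genes became 754 with array weights. In these 2 settings the 4531 genes of SB216763 minus DMSO became 3652 and 3849. The 5333 of CHIR99021 minus DMSO became 5483 and 6032, and the 5059 of Bio-Acetoxime minus DMSO became 5062 and 5579. The standard deviation of the replicate difference over genes was 0.172 for SB216763, 0.144 for DMSO, 0.136 for CHIR99021 and 0.138 for Bio-Acetoxime. Whether this spread is the cause was not tested. With camera's estimated correlation 0 lists were called in each of the 6 contrasts, against 4, 7, 6, 2, 4 and 4 at an unadjusted p under 0.05. With fry 6 lists were called for CHIR99021 minus SB216763 and 5 for CHIR99021 minus Bio-Acetoxime, against 10 and 10; fry does not set a list against other genes.

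With each of the 8 arrays left out in turn, which leaves a lone array assumed to vary like the other groups, counts ranged from 26 to 263 for CHIR99021 minus SB216763, from 196 to 613 for CHIR99021 minus Bio-Acetoxime and from 458 to 1041 for SB216763 minus Bio-Acetoxime. Against DMSO they ranged from 3896 to 5706 for CHIR99021, from 3052 to 4194 for SB216763 and from 3591 to 5390 for Bio-Acetoxime, and shared genes from 2190 to 2991. The correlations stayed between 0.893 and 0.932, 0.901 and 0.924, and 0.848 and 0.880. Over these fits, 403 results for single genes lost their call and 4 gained it, against 3457 that stayed on their side of the threshold, and 21 list results lost it and 7 gained it, against 1076. Against DMSO and for the shared genes each of these counts stayed within 1.5 times that of all arrays, while 6, 4 and 3 of the 8 did not for CHIR99021 minus SB216763, CHIR99021 minus Bio-Acetoxime and SB216763 minus Bio-Acetoxime.

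The replicate numbers do not pair the arrays: correlations of the deviations of same-numbered arrays across genes ran from -0.04 to 0.12. With the replicate block the counts were 5268, 4438 and 4967 against DMSO, 311, 568 and 1168 between inhibitors and 3127 shared, 468 of the results for single genes stayed on their side of the threshold and 15 lost their call, and no list call changed.

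Not run were both filters on dim genes and the choice of the brightest probe set, which need the signal level, eBayes with a trend, and a repeat of the quantile normalisation, which on centred values would force the deviations of all arrays to a common distribution. The values are used here with no filter, which was itself among the alternatives. The signal over background is not known from centred values, so weakly expressed genes cannot be told from silent ones.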

Other observations

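The test of a common response was set before the result was seen, while the further correlations and the gene AXIN2 were chosen after.

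AXIN2, a negative regulator of Wnt signalling and a direct target of ß-catenin in many cell types, rose by 0.75 ± 0.08 with CHIR99021, 0.87 ± 0.08 with SB216763 and 0.58 ± 0.08 with Bio-Acetoxime on the log2 scale (adjusted p = 8.60e-05, 4.76e-05 and 4.40e-04 with limma). It is a member of the Wnt target list, in which MYC fell with all 3.

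The differences between inhibitors may in part be a single response at different strengths. Across genes, which are not independent replicates, the difference CHIR99021 minus SB216763 correlated at r = 0.458 with the response to Bio-Acetoxime against DMSO, which shares no array with it, so that 21.0% of the variance is in common. Of the other differences, CHIR99021 minus Bio-Acetoxime correlated at r = 0.181 with the response to SB216763, and SB216763 minus Bio-Acetoxime at r = -0.231 with that to CHIR99021. Strength along a shared response therefore leaves most of each difference undescribed, and the doses were not matched.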
